A study of Mus musculus with 22 samples.

How the data were processed

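Gene expression was measured in 22 mouse samples on Affymetrix arrays of 45101 probe sets. A2C12 is a lung tumour cell line from a mouse carrying c-myc and c-raf transgenes. Its side population is the cell fraction that excludes the DNA dye Hoechst, which was sorted by flow cytometry, per the labels' protocols. The groups were 3 samples of untreated sorted cells, 3 samples of sorted cells treated before the sort with a monoclonal antibody against mouse EpCAM (100 µg/ml for 48 h), and lung tissue of non-transgenic C57BL/6 mice, 8 labelled male and 8 labelled female. The labels call the samples of each group biological replicates.

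The deposited values are intensities on a linear scale, summarized per probe set with PLIER, per the submitters' processing notes. The version of PLIER, its settings and any scaling between arrays are not stated in the sources used here. The mean intensity per array lay between 268.55 and 311.11, and the median between 39.3 and 40.6 on the cell arrays and between 47.9 and 54.6 on the lung arrays. No read depth applies to arrays, and the number of arrays limits the precision.

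The 64 control probe sets were left out of the tests, which left 45037. The probe set table supplied with the series listed 34945 of these with 1 gene symbol and 932 with several, and 9160 were not listed. Each of 18193 genes was represented by 1 probe set, the one with the highest mean over the 22 arrays, avoiding sets of the cross-hybridizing type where another was present. The intensities were transformed as log2(intensity + 16). Array quartiles differed by more than the limit set beforehand, so all 22 arrays were quantile normalized. Folds of genes near background depend on the offset of 16. A gene was tested if it lay above the 40th percentile of the array on at least 3 of the compared arrays.

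Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with intensity, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The antibody comparison used the 6 cell arrays. Each cell group was compared with the mean of male and female lung in a fit of all 4 groups, and a change of at least 2-fold was also required. In that fit each gene has a variance shared by the 4 groups, to which the 16 lung arrays contribute most. The cells are preparations of a single line, so these SE and p do not measure spread between tumours. Female and male lung were compared on the 16 lung arrays. Standard errors (SE) are those of the model, and intensities are given with the SD of the arrays.

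The 53 gene lists and cell type marker sets, the tests, the comparisons and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison that had members enough to test. They were tested again with an estimated correlation and with fry, which asks whether the list's own genes move one way on balance. The named genes were Epcam, the 10 with the largest rise and the 10 with the largest fall among called genes whose groups do not overlap, and up to 4 members with the largest change of each list described. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named as values. Predicted genes may be left out. Which lists are described was decided after their values were seen, as were the definition of switching probe sets (a gap of more than 1 on the log2 scale between the cell arrays, with the low side under an intensity of 40) and the settings called added below. The criterion for whether the second Epcam probe set follows the first across lung was made stricter after its value was seen, which moved the reading of that test from favouring an effect of summarization to undecided.

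The fits were tested on simulated values with 50 changed genes per size and noise independent between genes, without the normalization, probe set choice or filter. Recovery was counted on the adjusted p alone. For the cells against lung the 2-fold requirement was not applied, so the shares below do not give the recovery of the reported rule. For the antibody comparison, with 12722 genes, 8% of changes of 0.5 on the log2 scale, 84% of changes of 1 and 100% of changes of 2 were recovered, with 6 false calls. For untreated cells against lung, with 15184 genes, the shares were 56%, 94% and 98%, with 12 false calls. For antibody-treated cells against lung, with 15125 genes, they were 52%, 92% and 96%, with 9 false calls. For female against male lung, with 14397 genes, they were 74%, 98% and 100%, with 8 false calls.

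The alternatives fixed beforehand were no normalization, median centring, offsets of 1 and 64, no filter and a 60th percentile filter, the mean of a gene's probe sets, all probe sets as features, no variance trend, array weights, the ordinary t statistic of the same model, the replicate number as a block, other sets of arrays in the fit and leaving out each cell array in turn. The settings added after seeing the data left out the arrays labelled male 3 and 4, treated lung replicates 1 to 4 and 5 to 8 as array sets, left out switching probe sets, or normalized the 6 cell arrays alone. Replicate numbers were not used as pairs in the comparisons reported. Genes listed on no probe set, and probe sets naming several genes, were not analysed here.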

Results

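Messenger RNA of 22 samples was measured as probe set intensity on arrays. The samples were 3 untreated and 3 antibody-treated preparations of sorted A2C12 side population cells and 16 lungs, 8 labelled male and 8 labelled female. Replicate arrays correlated across genes at 0.984 to 0.989 in untreated cells, 0.974 to 0.985 in antibody-treated cells, 0.967 to 0.993 in male-labelled and 0.984 to 0.995 in female-labelled lung. Genes are not independent replicates, so these values describe the arrays only. Log2 changes refer to log2(intensity + 16) after quantile normalization, and adjusted p are those of limma, or of its camera test for gene lists.

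The comparison of untreated sorted cells with lung asked how a dye-excluding fraction of a lung tumour line differed from normal lung. The series holds no unsorted cells of the line, so differences cannot be assigned to the dye-excluding fraction rather than to the line. Nor does the design separate them from the mix of cell types in lung tissue. Sorted cells carried high transcript levels of the chemokine gene Ccl2, the transcription factor genes Sox9 and Eya4 and the cell cycle inhibitor gene Cdkn2a. The main secretory and surfactant transcripts of lung were far lower in them. Sox9 (Entrez gene 20682) read 29986 ± 5817 (SD, n = 3) in untreated cells and 307 ± 63.8 (SD, n = 16) in lung, a log2 change of 5.73 ± 0.19 (SE; limma adjusted p = 1.27e-18). Quantile normalization lowered the changes of Sox9 and Eya4, which were 6.54 and 6.99 without it. Ccl2 read 3647 ± 1964 (SD, n = 3) against 18.4 ± 9.49 (SD, n = 16), a change of 6.65 ± 0.26. Eya4 rose by 6.14, the adhesion gene Chl1 by 6.11, Mgarp by 5.85, the chemokine gene Ccl7 by 5.80, the BMP antagonist gene Grem1 by 5.58, Cdkn2a by 5.39 and Syt13 by 5.31. The urokinase gene Plau rose by 6.57 ± 0.87, from 32.2 ± 7.41 (SD, n = 16), but its probe set read 17.3 on 1 of the 3 antibody-treated arrays and 13384 on another. A second Plau probe set did not rise, with 31.8 ± 4.79 (SD, n = 3) in untreated cells and 33.6 ± 3.88 (SD, n = 16) in lung. Of 15184 genes tested, 6233 passed, 2659 higher and 3574 lower.

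The largest falls were in genes of lung secretory and alveolar cells and of B cells. Scgb1a1, the main secretory product of club cells, changed by -9.49 ± 0.15 (SE), from 13226 ± 679 (SD, n = 16) to 7.13 ± 7.93 (SD, n = 3). Cyp2f2 (-8.99), Scgb3a2 (-8.94) and the surfactant genes Sftpa1 (-8.59), Sftpc (-8.40) and Sftpb (-8.34) fell likewise, as did Lyz2 (-8.59), Wfdc2 (-8.51) and the immunoglobulin genes Igkv8-30 (-8.81) and Ighm (-8.45). Of the club cell markers, 8 of 9 measured fell, of alveolar type 1 markers 11 of 12 and of alveolar type 2 markers 13 of 14. Examples of type 1 markers were Cldn18 (-7.31) and Ager (-7.01). The camera adjusted p were 4.21e-06, 1.98e-06 and 8.32e-08, and with an estimated correlation the adjusted p = 0.00856, 0.00627 and 0.107. All 15 endothelial markers fell (adjusted p = 4.57e-10, and adjusted p = 0.103 with an estimated correlation), among them Cdh5 (-7.59), Calcrl (-7.45) and Ramp2 (-7.43).

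Epcam encodes the antigen of the antibody used in the series, and its 2 probe sets disagreed on its level in the sorted cells. The chosen probe set of Epcam (Entrez gene 17075) read 3.19 ± 2.88 (SD, n = 3) in untreated cells and 4.22 ± 6.02 (SD, n = 3) in antibody-treated cells. Lung read 925 ± 371 (SD, n = 8) in male-labelled and 759 ± 54.5 (SD, n = 8) in female-labelled samples. The log2 change against lung was -5.36 ± 0.21 (SE; limma adjusted p = 3.86e-17) for untreated and -5.32 ± 0.21 (adjusted p = 4.73e-17) for antibody-treated cells. A second Epcam probe set, of the type that can cross-hybridize, went the other way, with 305 ± 41.5 (SD, n = 3) in untreated cells and 201 ± 29.4 (SD, n = 16) in lung.

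Other epithelial genes were lower in the cells than in lung. Of 23 measured epithelial adhesion and keratin genes, 20 fell, 0 rose and 3 did not pass, with a median change of -3.87 (camera adjusted p = 1.61e-08, and adjusted p = 0.0612 with an estimated correlation). The list includes Epcam, whose chosen probe set is among those that fell. Examples were the keratin gene Krt7 (-6.94) and the tight junction genes Cldn3 (-6.83) and Cldn7 (-5.45). Of 16 genes of Epcam and its membrane and signalling partners, 8 fell, Epcam itself included, and 1 rose (adjusted p = 0.00604, and adjusted p = 0.156 with an estimated correlation). Examples were the protease inhibitor gene Spint2 at -7.13 and the tetraspanin gene Tspan8 at -4.72. The member that rose was the protease gene Adam10 (1.03), named after its values were seen. Mesenchymal genes went both ways. N-cadherin gene Cdh2 rose by 5.03 and Twist1 by 3.46, the smooth muscle gene Tagln changed by -6.31, and 8 of 21 rose and 7 fell (camera adjusted p = 0.429).

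**Figure D1:**
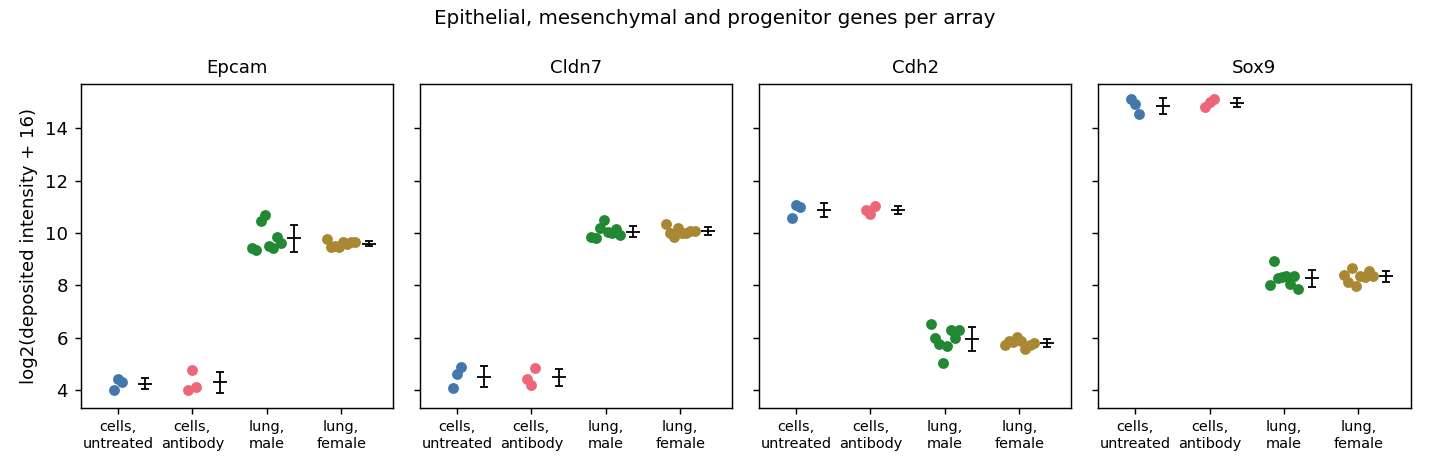
Intensity (log2 of deposited intensity + 16) of the epithelial genes Epcam and Cldn7, the mesenchymal gene Cdh2 and the transcription factor gene Sox9 per array. Points are arrays and bars are group mean and SD. The chosen probe set of Epcam, the one shown, read at most 11.1 on the 6 cell arrays and at least 644 on the 16 lung arrays.

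Genes of cell division and growth were higher in the cells than in lung. All 27 measured genes of DNA replication rose, with a median of 2.74 (camera adjusted p = 2.30e-10, and adjusted p = 0.156 with an estimated correlation), for example Uhrf1 (4.32), Tk1 (4.31) and Rrm2 (4.10). All 25 mitosis genes rose, with a median of 3.46 (adjusted p = 1.10e-09, and adjusted p = 0.225 with an estimated correlation), for example Birc5 (4.94), Cdk1 (4.31) and Top2a (4.16). Of 25 genes of MYC-driven ribosome biogenesis, 20 rose and 0 fell (adjusted p = 9.26e-08, and adjusted p = 0.107 with an estimated correlation), with Nop58 at 3.00. Wdr12 of that list rose by 3.00 on its chosen probe set while a second set changed by -1.27. Amino acid response genes under ATF4 rose in 15 of 21 cases (adjusted p = 5.41e-05, and adjusted p = 0.178 with an estimated correlation), with the serine synthesis genes Psat1 (4.63) and Phgdh (3.58) and the stress gene Trib3 (4.29). Cholesterol synthesis genes rose in 11 of 19 cases (adjusted p = 9.55e-05, and adjusted p = 0.273 with an estimated correlation), with Cyp51 at 2.52 and Sqle at 2.02.

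Immune signalling genes went apart. Of 22 NF-kappaB target genes, 11 rose and 4 fell (camera adjusted p = 0.173), with Cxcl1 at 4.23 besides Ccl2 and Ccl7, and the adhesion gene Icam1 at -4.04. Interferon-stimulated genes fell in 14 of 22 cases and rose in 0 (adjusted p = 3.57e-05, and adjusted p = 0.178 with an estimated correlation), with Rtp4 at -5.47 and Ifit1 at -4.08. Genes of MHC class I presentation fell in 10 of 13 cases (adjusted p = 0.000646, and adjusted p = 0.107 with an estimated correlation), with the immunoproteasome genes Psmb9 at -4.14 and Psmb8 at -4.11.

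Transporter and stem cell marker lists held genes that rose and genes that fell, and did not pass camera. Among 14 transporters of the ABC family, 4 rose and 4 fell (camera adjusted p = 0.685), with the drug efflux gene Abcb1b at 3.29 and the sterol exporter gene Abcg1 at -5.27. Abcg2, named here after its values were seen because its product exports the dye, read 215 ± 39.1 (SD, n = 3) in untreated cells and 186 ± 33.8 (SD, n = 16) in lung and did not reach a 2-fold change (0.42 ± 0.12, SE). Of 15 stem and progenitor markers, 4 rose and 8 fell (adjusted p = 0.209), with Aldh1a1 at -7.69, Alcam at -7.51, Prom1 at -5.31 and Kit at -4.82. The 4 that rose, named after their values were seen, were Aldh1a3 (3.30), Procr (2.66), Lgr5 (2.05) and Aldh3a1 (1.82). The fry test, which passed 49 of 52 lists of this comparison, had transporters and stem and progenitor markers lower on balance (fry adjusted p = 1.035e-06 and 5.11e-17). By fry, NF-kappaB targets and mesenchymal genes were higher on balance (fry adjusted p = 6.95e-05 and 3.48e-05). For every list of this comparison described here, the members passing when adjusted over the list alone were as many as over all genes.

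**Figure D2:**
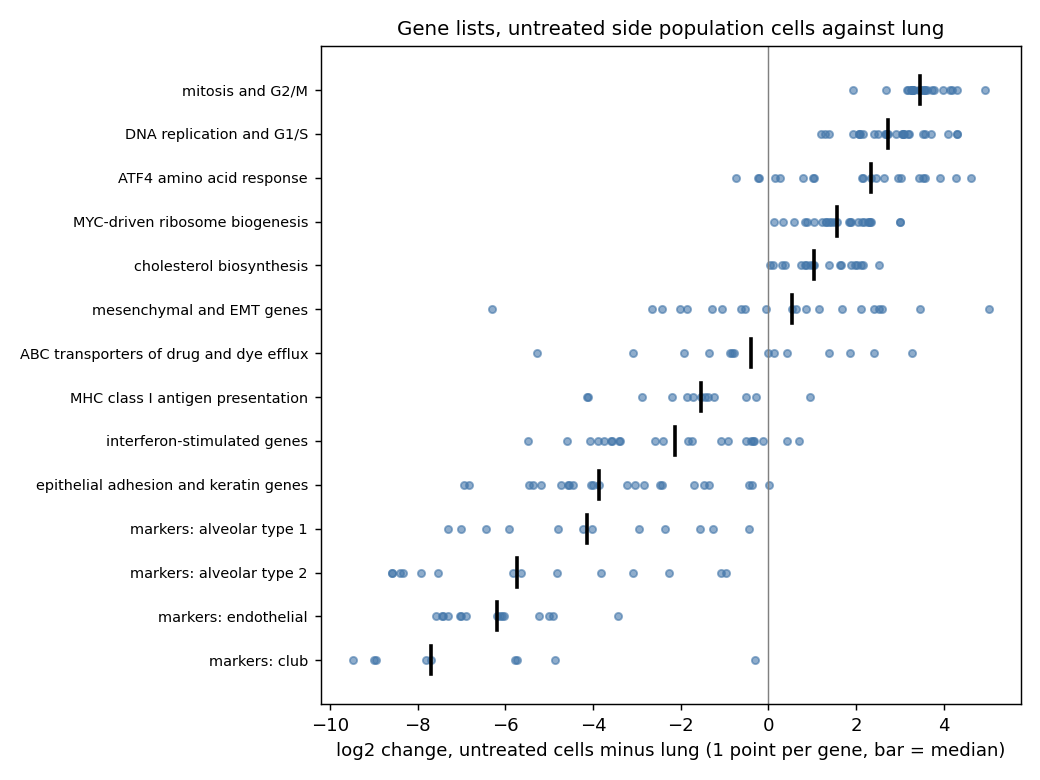
Log2 change of untreated cells minus lung for the members of gene lists, with a point per gene and a bar at the median. The median of the mitosis genes was 3.46 and that of the epithelial adhesion and keratin genes -3.87.

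The cell and lung arrays also differed in their labelling controls. The poly-A control dap, added to RNA before labelling, read 438 to 761 on the 6 cell arrays and at most 3.70 on the 16 lung arrays, so a difference in labelling and the difference between cells and lung cannot be told apart. The log2 ratio of 3' to 5' Gapdh probe sets, a measure of RNA quality, was -0.13 to 0.40 on cell arrays and 0.22 to 1.01 on lung arrays, while that of Actb was 0.22 to 1.21 and 0.28 to 0.90. Without normalization the median change of all genes was -0.15 and with median centring 0.12, against 0.01 as reported, and the share of called genes that were higher was 34.9%, 48.3% and 42.7%.

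Antibody-treated cells against lung asked whether the same differences held after exposure to the antibody. Of 15125 genes, 6147 passed, 2560 higher and 3587 lower. Among genes tested in both comparisons, 2424 were higher in both (441 expected from independent lists) and 3402 were lower in both (851 expected), and 1 gene, Il1f5, was called in opposite directions (1.85 and -1.16), on a probe set described with the antibody comparison. The rises included Ccl2 (6.78 ± 0.26, SE), Eya4 (6.22), Sox9 (5.65) and the AP-1 gene Fosl1 (5.40). Vcan rose by 5.17 on its chosen probe set while a second set changed by -2.74. Scgb1a1 (-9.02 ± 0.15, SE), Cyp2f2 (-8.87), Inmt (-8.31) and Bpifa1 (-8.30) fell. Of the epithelial list 20 of 23 fell (camera adjusted p = 2.35e-08, and adjusted p = 0.0658 with an estimated correlation), all 27 replication genes rose (adjusted p = 1.25e-10, and adjusted p = 0.157 with an estimated correlation), and 9 of 19 cholesterol genes rose (adjusted p = 0.000257, and adjusted p = 0.306 with an estimated correlation). Of the list of Epcam and its partners, 8 of 16 fell and 1 rose (adjusted p = 0.00783, and adjusted p = 0.169 with an estimated correlation). Epcam itself was counted among those that fell in this list and in the epithelial list. Both comparisons used the same 16 lung arrays. With unchanged groups simulated on those arrays the changes correlated at 0.160 across genes, and with each comparison given its own lung arrays the measured correlation was 0.985, against 0.994 with shared arrays.

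The comparison of antibody-treated with untreated cells asked what 48 h of antibody changed in the sorted fraction. Transcript levels were close between the groups. Of 12722 genes, 3 passed, all lower after antibody. Il1f5, an interleukin-1 family gene, changed by -3.02 ± 0.12 (SE; limma adjusted p = 3.29e-05), from 205 ± 9.85 (SD, n = 3) to 12.2 ± 0.73 (SD, n = 3). Omg, a myelin glycoprotein gene, changed by -3.43 ± 0.21 (adjusted p = 0.000606), from 212 ± 14.7 (SD, n = 3) to 6.88 ± 5.95 (SD, n = 3). The clone 2610037D02Rik changed by -2.34 ± 0.25 (adjusted p = 0.0367), from 73.9 ± 11.3 (SD, n = 3) to 4.42 ± 6.83 (SD, n = 3).

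Each of these 3 genes was read by a probe set that switched between near 0 and a high level, and 410 probe sets did so across the 6 cell arrays. A large change between the groups from near background also meets this definition. A second probe set of 2610037D02Rik read 31.6 ± 4.37 (SD, n = 3) in untreated and 33.4 ± 0.37 (SD, n = 3) in antibody-treated cells. In the full comparison 100 genes had an unadjusted p under 0.05, with 636 expected by chance. The groups did not overlap for 375 genes (2.95%), where chance gives 10%. The 95% interval of the change lay within 2-fold for 97.3% of genes.

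**Figure D3:**
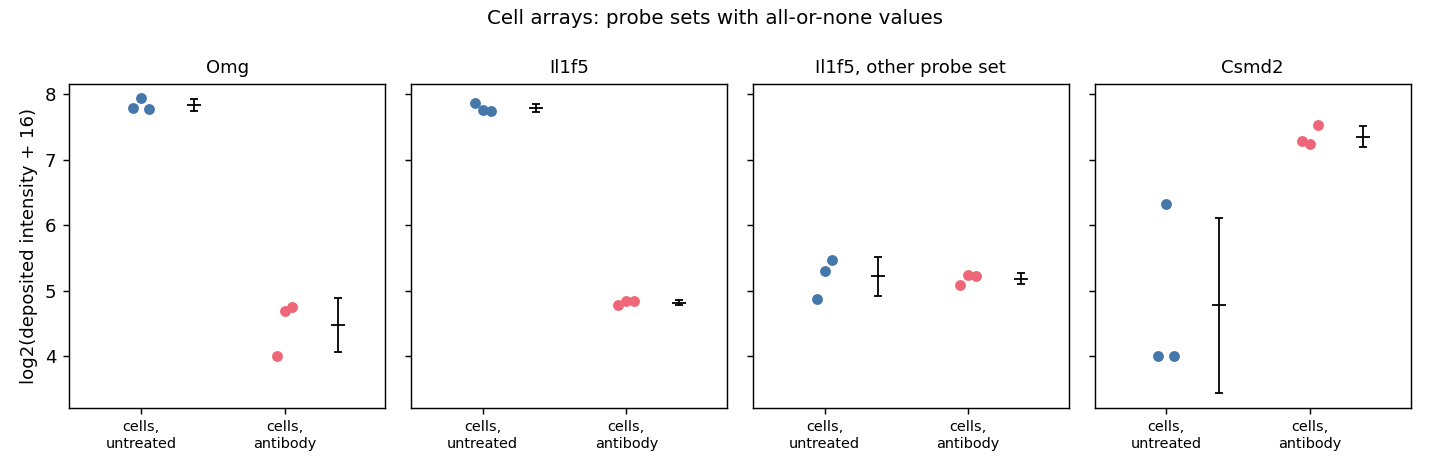
Intensity (log2 of deposited intensity + 16) of Omg, Il1f5, a second Il1f5 probe set and Csmd2 per cell array, with points for arrays and bars for group mean and SD. Csmd2 was not a called gene, and the called clone 2610037D02Rik is not shown. Il1f5 read 12.2 ± 0.73 (SD, n = 3) after antibody on its chosen set, and 20.3 ± 2.04 (SD, n = 3) on its second set.

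The genes with the smallest p among higher values did not pass, with limma adjusted p = 0.99996 for each. Their log2 differences were 0.66 for the scavenger receptor gene Msr1, 2.67 ± 0.59 (SE) for Csmd2, 0.95 for Pyroxd2, 0.59 for Cyp4b1 and 0.49 for Polr3f. Among lower values Chil4 had -0.86 and Magea4 -0.74, with the same adjusted p. The chosen probe set of Epcam was below the intensity filter in both groups.

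Gene lists differed by small amounts. Of 43 lists, 7 passed camera and 0 passed with an estimated correlation. Genes of RAF, MEK and ERK output, the pathway of one of the line's transgenes, had a median difference of 0.09, with positive values in 16 of 19 genes (camera adjusted p = 0.00202, and adjusted p = 0.857 with an estimated correlation), for example Phlda1 at 0.38 and Hbegf at 0.37. Alveolar type 2 markers had a median of 0.16, positive in 6 of 6 (adjusted p = 0.00202, and adjusted p = 0.857 with an estimated correlation), with Sftpc at 0.71 and Cxcl15 at 0.30. Sftpc read 16.6 ± 6.45 (SD, n = 3) in untreated and 35.8 ± 16.1 (SD, n = 3) in antibody-treated cells, so near background that its difference depends on the offset. MHC class I genes had a median of 0.10, positive in 11 of 12 (adjusted p = 0.00320, and adjusted p = 0.857 with an estimated correlation), with Psmb8 at 0.37 and Psmb9 at 0.30. Cholesterol synthesis genes had a median of -0.13, positive in 1 of 19 (adjusted p = 0.00388, and adjusted p = 0.857 with an estimated correlation), with Idi1 at -0.23 and Mvk at -0.22. The other 3 that passed were MYC-driven ribosome biogenesis (median 0.057), glycolysis (-0.099) and the hypoxia response (-0.11), with camera adjusted p = 0.0369 and adjusted p = 0.857 with an estimated correlation for each. Of the 12 EpCAM partners and 13 ABC transporters tested, 0 passed (camera adjusted p = 0.447 and 0.785), with Tspan8 at 0.52, Abcc4 at 0.36 and Abcg2 at -0.18. In these lists, 0 genes passed over all genes and 0 when adjusted over the list alone.

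Leaving out single arrays ended the camera calls of the 4 lists with the smallest p, and the other 3 were not run this way. The camera adjusted p was 0.581 for RAF, MEK and ERK output without untreated 2, 0.435 for MHC class I without antibody 1, 0.0837 and 0.378 for alveolar type 2 without antibody 2 and 3, and 0.456, 0.0918 and 0.876 for cholesterol synthesis without untreated 2, untreated 3 and antibody 2.

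Female and male lung were compared to see how alike the control tissue was and whether the labels of sex matched the transcripts. Xist, transcribed from the inactive X chromosome, read 1225 to 1951 on the 8 female arrays and 12.7 to 24.0 on 6 of the 8 male-labelled arrays. The arrays labelled male 3 and male 4 read 1512 and 1583. The Y-linked gene Uty read 722 to 1253 on the other 6 male-labelled arrays, and 8.27 and 9.46 on the arrays labelled male 3 and male 4. Eif2s3y and Kdm5d, also on the Y chromosome, read 2.79 and 0.56 on the array labelled male 3 and 3.64 and 3.43 on the array labelled male 4. The 6 cell arrays read 1758 to 2443 for Xist and 4.24 to 12.1 for Uty.

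**Figure D4:**
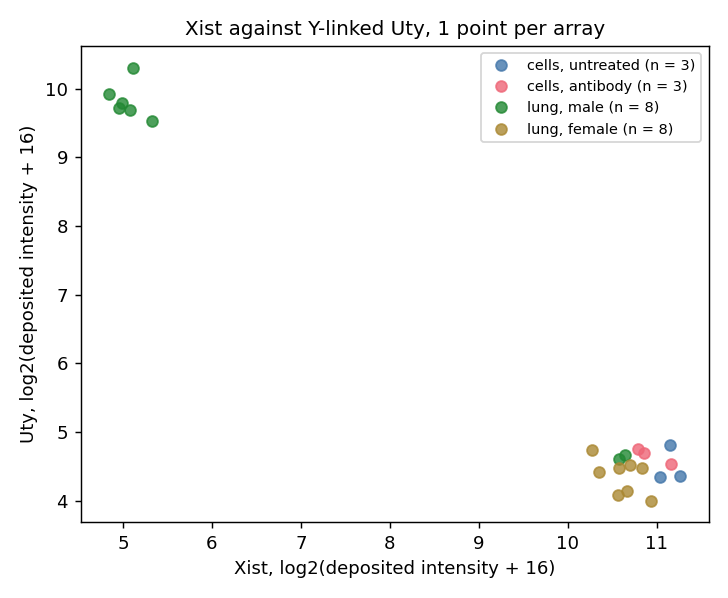
Intensity (log2 of deposited intensity + 16) of Xist against that of the Y-linked gene Uty, with a point for each cell and lung array. The arrays labelled male 3 and male 4 read 1512 and 1583 for Xist, within the range of 1225 to 1951 on the female arrays.

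With all 16 lung arrays as labelled, 7 of 14397 genes passed. The lymphocyte genes Thy1 (0.73 ± 0.09, SE; limma adjusted p = 0.00235) and Lat (0.56) and the sialyltransferase gene St8sia2 (0.53) were higher in female lung. Pla2g7 (-0.85), Xdh (-0.40), Nampt (-0.28) and Uty (-4.17 ± 0.75, SE; adjusted p = 0.0476) were lower. Among genes that did not pass, Xist had a difference of 4.21 ± 0.80 (SE; adjusted p = 0.0535), Ctsw 0.53, Gpcpd1 -0.46 and Epcam -0.18 (adjusted p = 0.728). Without the arrays labelled male 3 and 4, a setting added after seeing the data, 45 genes passed, 15 higher and 30 lower, among them the 7. Of these 10 lie on the X and 3 on the Y chromosome, with Xist at 5.61, Uty at -5.48 and Eif2s3y at -4.66.

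Some gene lists also shifted between female and male lung. Of 51 lists, 11 passed camera, 4 passed fry and 0 passed with an estimated correlation. The 4 are described here. All 12 T and NK cell markers had positive differences, with a median of 0.44 (camera adjusted p = 9.54e-12, and adjusted p = 0.0603 with an estimated correlation), and 0 passed over all genes and 9 when adjusted over the list alone. Ccl5 had 0.68, Gzma 0.65 and Nkg7 0.61. Antioxidant genes under NRF2 had a median of -0.21 (adjusted p = 7.18e-07, and adjusted p = 0.0603 with an estimated correlation), with 0 passing over all genes and 8 adjusted over the list alone, for example Nqo1 (-0.95) and Hmox1 (-0.89). X-linked genes that escape inactivation had a median of 0.45 (adjusted p = 1.58e-09, and adjusted p = 0.0603 with an estimated correlation), with 0 passing over all genes and 7 adjusted over the list alone. Of 4 measured genes of the list of Y-linked genes and Xist, 1 fell over all genes, and 1 rose and 3 fell when adjusted over the list alone (adjusted p = 0.00489, and adjusted p = 0.0603 with an estimated correlation).

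Lung replicates 1 to 4 and 5 to 8 differed as array sets. Deviations from the group mean, which centring makes negative on average, correlated across genes at a mean of 0.214 within and -0.404 between the sets in female lung, and at 0.163 and -0.329 in male-labelled lung. In female lung every pair within a set (at least -0.0403) exceeded every pair between sets (at most -0.273). In male-labelled lung the pairs overlapped (at least -0.369 within, at most 0.127 between). With the array set as a block 41 genes passed. In replicates 5 to 8 alone the T and NK markers had a median of 0.49 (camera adjusted p = 1.77e-11) and the NRF2 genes -0.27 (adjusted p = 6.91e-07). In replicates 1 to 4 without the arrays labelled male 3 and 4 the medians were 0.064 (adjusted p = 0.549) and -0.030 (adjusted p = 0.666). The latter set holds only male 1 and male 2 on the male side. The difference between the sets was not tested. For the counts and correlations that follow, the arrays labelled male 3 and 4 were left out. Of genes called in each set, 13 were called in both in the same direction, where independent lists would give 3.05, and 2 in opposite directions. Of the 13, 6 lie on the X or Y chromosome, all of them on the X. With only male 1 and male 2 left in replicates 1 to 4, Y-linked genes could not pass the filter of 3 arrays there. Across all genes the changes of the sets correlated at 0.0707, and at 0.0230 without genes of the X and Y chromosomes.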

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

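The splits of the lung comparisons and the test on all probe sets near 0 in the cells were set before their results were seen, as were the splits with equal numbers from each lung array set, which were added later, and the other tests in this part were chosen after.

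The 3 genes called after antibody, Il1f5 (-3.02), Omg (-3.43) and 2610037D02Rik (-2.34), differed between the cell groups as tested by limma, on probe sets that switch between near 0 and a high level. Of 62 switching probe sets that divided the 6 cell arrays 3 against 3, 5 followed the treatment, while the other 9 divisions held 6.33 on average and 14 at most. With a gap of more than 2 there were 33 such sets, of which 3 followed the treatment, against 3.33 on average and 8 at most. For 104 genes with a bright second probe set the switching sets moved by a median of 2.59 and the second sets by 0.048 (95% interval -0.0024 to 0.099). Second sets that switched too, or were not bright on all 6 cell arrays, had been left out. Sets that lost their signal along with the first could therefore not count, and these medians do not decide whether RNA differed. By the counts of the divisions, switching without regard to treatment may account for the calls. An antibody effect stays open and both cannot be told apart, since only 1 of the 3 genes, 2610037D02Rik, has a second probe set above the 40th percentile on all 6 arrays, and that set, which moved by 0.073 and so speaks against an effect on this gene, read at most 36.6, under the median of each cell array and too near background to exclude one. Divisions of 6 arrays are too few for a share under 0.05: 2 of 10, the real one included, called at least the real 3. The highest other called 101, and the remaining 8 called 0 to 2. At an unadjusted p under 0.05, with 636 genes expected by chance, the real division had 100. Of the other 9, some had 771, 878, 1022, 1194 and 2154, and the rest 103 to 335. Several divisions thus point to a structure of the cell samples that does not follow treatment, and its source was not tested.

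The arrays labelled male 3 and male 4 carried female-like Xist and Y-linked values. A swap with female-labelled arrays is argued against, since 0 of the 8 reached the lowest other male-labelled array for a Y-linked gene. A mixture of male and female RNA is argued against as well, since the highest Y-linked value on either array was 2.18% of the mean of the other male-labelled arrays. Female tissue under a male label is consistent with 5 of 8 genes that escape X inactivation lying nearer the female mean on both arrays on normalized log2 values (6 of 8 on deposited intensities). Where such tissue came from stays open, and no biological explanation was tested.

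The chosen probe set of Epcam was near 0 in the cells, whose treatment was directed at its product. A probe set that detects no Epcam RNA is argued against by its lowest lung reading, 644. Summarization that sets probe sets to near 0 is argued against for such sets as a class, second sets of the cross-hybridizing type left out. Of 163 genes, 57 had a bright second probe set of another type, and 96.5% of these fell by at least 1 on the log2 scale on it too. The second set of Epcam is of the type left out, so these genes hold no pair like that of Epcam. For Epcam alone summarization stays open: the second set was 0.73 higher in cells than in lung, and over 16 lung arrays it followed the first with Pearson r = 0.524 (permutation p = 0.0337, 0.0673 adjusted over 2 tests) and Spearman rho = 0.268 (permutation p = 0.313), a relation that rests on the 2 farthest arrays, without which r = 0.102. A low epithelial adhesion programme of the cells is a candidate explanation in line with 19 of 22 other epithelial genes being lower in antibody-treated cells than in lung, as a hypothesis found on these data.

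Other divisions of the arrays tested whether chance gives counts as large as those of the lung comparisons. Of 100 divisions, the real one alone reached 6233 genes for untreated cells against lung (1 of 100; highest other 3497) and 6147 for antibody-treated cells (1 of 100; highest other 3496), and 7 for female against male lung (1 of 100; highest other 1). The share cannot fall under 1 of 100 here, so chance is made unlikely for these counts but is not excluded. For the cells, every other division mixed cell and lung arrays, so the counts show only that cells and lung differ. Between female and male lung 9 other splits had at least as many genes at an unadjusted p under 0.05 as the real 1517, up to 1980. Among 100 splits with equal numbers from lung replicates 1 to 4 and 5 to 8, as in the real one, the real one alone reached 7 genes (1 of 100; highest other 0) and, with the array set as a block, 41 (1 of 100; highest other 0), and 0 others had as many at an unadjusted p under 0.05.

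Control RNAs outside the gene comparisons stood apart. The poly-A controls read a median of 684 (dap), 71.4 (lys), 148 (phe) and 138 (thr) on the 6 cell arrays, and at most 3.70, 11.2, 10.4 and 7.94 on the 16 lung arrays.

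Single lung arrays far from the 7 others of their group were found for 21 of 306 pairs of a named gene and a group, where chance gives 15.3. The distances were taken on normalized log2 values, and the values below are deposited intensities, on which some of these arrays lie close to the others. Of these, 7 were on female 1: Ereg at 256 (others at most 17.2), Napsa at 4336, Spint2 at 3115, Osgin1 at 213 and Polr3f at 139 above the others, and Gzma at 821 and Rtp4 at 696 under them. Female 2 was low for Cd9 (4275) and Egfl7 (1687), female 3 for Sqle (429), female 6 for Cxcl15 (6061) and female 8 for Trib3 (29.4). Female 5 was high for Kdr (2324) and female 6 for Nampt (750). Male 2 was high for Tap1 (469) and low for Scgb1a1 (11638), and male 6 was low for Gpcpd1 (520). Scgb1a1 was the brightest probe set on the 7 other male-labelled arrays, where normalization gave it the same value. Its flag therefore reflects rank alone, and the chance rate does not apply to it. The array labelled male 3 was low for Bpifa1 (1259, others at least 5764) and Prom1 (552). The array labelled male 4 was low for Kdr (943) and high for 2610037D02Rik (83.6).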

How the results depend on the processing

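The settings that leave out switching probe sets or lung arrays, use array sets or normalize the cell arrays alone were chosen after seeing the data. No named gene past the threshold and no described list reversed its direction under a setting run. Among all genes called against lung, up to 7 for untreated cells (offset of 1) and up to 6 for antibody-treated cells (mean of probe sets) were called in the opposite direction. Of 183 and 182 other probe sets of named genes and list members, 13 in each of these comparisons went the opposite way (adjusted p under 0.05). For antibody against untreated cells the 3 calls became 1 with an offset of 1, 1 with the ordinary t statistic (Il1f5 in both) and 0 without switching probe sets, a setting that leaves out the 3 genes themselves and so does not bear on their stability. Leaving out single cell arrays gave 0 to 3 calls: 1 without untreated 1 (Zfp787, 3.89, limma adjusted p = 0.000424), 2 without untreated 2 (Csmd2, 3.52, and Sel1l3, 5.56) and 0 without untreated 3, with 96 genes at an unadjusted p under 0.05, and 3, 3 and 2 without antibody 1, 2 and 3. The call of 2610037D02Rik ended without antibody 2 (adjusted p = 0.0920) and antibody 3 (adjusted p = 0.103), without a filter (adjusted p = 0.141), with the mean of probe sets (adjusted p = 0.218), with the replicate number as a block (adjusted p = 0.0961) and with all probe sets as features, and it was not tested with the 60th percentile filter. Il1f5 and Omg were called in each of these. With all probe sets, a set listed under no gene rose (3.80, adjusted p = 6.21e-05), and Lhpp was called without antibody 2 (2.47, adjusted p = 0.00603). Array weights gave 4 calls, the 3 genes and Chil4 (-0.945, limma adjusted p = 0.0458). Without an untreated array the 3 genes lay above the filter on too few arrays and were not tested, so these counts do not bear on them. All 7 list calls were lost with fry (adjusted p = 0.995 each). With the replicate number as a block 2 genes passed, but replicate numbers did not pair the samples, since correlations of deviations of the same number lay between -0.255 and 0.0749 in cells.

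Against lung, the count was 12944 for untreated and 12754 for antibody-treated cells with all probe sets as features, where more features were tested. Leaving out single cell arrays gave 5830 to 5935 and 5790 to 5839. Without the arrays labelled male 3 and 4 the counts were 6301 and 6196. Of the lists described for the cells against lung, camera calls with an estimated correlation held for alveolar type 1 and club cell markers. Stem and progenitor markers gained a camera call without untreated 1, 2 or 3 (adjusted p = 0.0308, 0.0465 and 0.0305), and NF-kappaB targets without untreated 3 (adjusted p = 0.0390).

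For female against male lung the 7 calls became 15 with median centring, 4 without a filter, 24 with the 60th percentile filter, 32 with all probe sets, 4 without the variance trend, 81 with array weights and 1 with the replicate number as a block. They became 45 without the arrays labelled male 3 and 4, 41 with the array set as a block, 181 in replicates 5 to 8 alone, 220 in replicates 1 to 4 alone and 470 in replicates 1 to 4 without the arrays labelled male 3 and 4. Except where stated, the cause was not tested. Over all settings, named genes kept their side of the threshold in 1673 of the values for untreated cells and 634 for antibody-treated cells against lung, with 0 lost, in 638 between the cell groups with 9 lost and 2 gained, and in 412 between the sexes with 33 lost and 76 gained. Genes that stayed uncalled count as kept, and settings that did not test a gene were not counted. Of the named genes, 3 of 34 between the cell groups and 7 of 33 between the sexes were called. The lost values fall on those called genes alone. Signal near background limits folds of genes that read near 0, since these depend on the offset.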

Other observations

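Markers of macrophages and genes of MHC class II presentation were also lower in untreated cells than in lung. All 13 measured macrophage markers fell against lung, among them Chil3 (-8.28 ± 0.17, SE) and the complement genes C1qa (-6.19) and C1qc (-5.41) (camera adjusted p = 1.98e-06, and adjusted p = 0.132 with an estimated correlation). All 6 genes of MHC class II presentation fell, with H2-Ab1 at -7.79, H2-Aa at -7.73 and Cd74 at -6.86 (adjusted p = 5.22e-05, and adjusted p = 0.0599 with an estimated correlation). Of 17 glycolysis genes 9 rose and 1 fell (adjusted p = 0.00822, and adjusted p = 0.156 with an estimated correlation), with the enzyme genes Pgam1 at 2.25, Tpi1 at 2.18 and Pgk1 at 1.97 and the regulator gene Pfkfb3 at -2.70. The members that passed when adjusted over the list alone were as many as over all genes.

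In lung, all 11 ciliated cell markers and all 15 endothelial markers had higher values in female-labelled samples, with medians of 0.29 (camera adjusted p = 5.16e-05, and adjusted p = 0.660 with an estimated correlation) and 0.22 (adjusted p = 4.47e-05, and adjusted p = 0.660 with an estimated correlation), and neither list passed fry (adjusted p = 0.335 each). No single member passed, over all genes or adjusted over the list alone. Foxj1, the regulator of motile cilia, had 0.52 and the endothelial gene Egfl7 0.43. Without the arrays labelled male 3 and 4 the medians were 0.11 (adjusted p = 0.0277) and 0.059 (adjusted p = 0.0613). In replicates 5 to 8 alone they were 0.21 (adjusted p = 0.00225) and 0.047 (adjusted p = 0.389), and in replicates 1 to 4 without the arrays labelled male 3 and 4 they were 0.13 and 0.085 (adjusted p = 0.549 each). The lists of this part and these settings were chosen after seeing the data.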
